A study of Homo sapiens with 18 samples.

How the data were processed

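RNA was measured in 18 libraries of 3 tissues under lunar or Earth gravity, 3 libraries per group, with groups taken from the sample titles. The labels give the organism as human, while the design text speaks of mice and the processing notes and gene symbols are those of mouse; the values are treated here as mouse. Per the labels' protocols, tissue was homogenised with zirconia beads in TRI Reagent, RNA was purified with a Direct-zol kit, and libraries were made with SMART-Seq mRNA and Nextera XT kits, which do not mark strand, so reads of a gene and an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, DRAGEN 4.3 and the builds GRCm39 and mm39 were used. How reads were assigned to genes is not given in the sources used here.

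The authors deposited 1 table of estimated counts per gene, not normalised, which they made with DRAGEN per the submitters' processing notes. It has 55414 rows, and 10.9% of its values are not whole. It names genes by symbol, and 1401 rows by an Ensembl identifier alone. A total of 79 names stood on more than 1 row (980 rows); these rows were summed, which left 54513 names, and sums were rounded to whole numbers. The reference genome at hand was human and was not used, so no coordinates are given. Library totals ran from 19662100 to 34373600 counts.

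Each tissue was fitted on its own 6 libraries in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10 and total of 15, TMM scaling, robust dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences between tissues were contrasts of 1 fit over all 18 libraries. A total of 42 gene lists and 14 marker lists, fixed before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, for lists with at least 5 genes tested. Rises and falls in a list count genes past the threshold over all genes tested, or over the list alone where so stated. The muscle share uses a list of skeletal muscle contractile genes. Overlaps were tested with Fisher's exact test. Figures were drawn with matplotlib 3.10.9.

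Genes are named by a rule fixed at the same time: per tissue, the 10 highest and 10 lowest fold changes among genes past the threshold with groups that do not overlap and at least 10 CPM in a group (with none, the 5 smallest p in each direction), up to 4 genes of smallest p per described list, a fixed set of tendon, muscle, fat, stress and clock genes, and the 5 smallest p in each direction of each interaction. Predicted genes and pseudogenes were passed over. Not all genes so chosen are described.

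The alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, at least 5 CPM in 3 libraries, limma-voom with quality weights, leaving out mitochondrial and haemoglobin genes, each library left out in turn, 1 fit of all libraries, the replicate number as a block, and the contractile gene level as a covariate in tendon and brown fat. Subtracting muscle reads, leaving out both lunar replicate 2 and Earth replicate 3 of the tendon, and a block of the replicate number within brown fat alone for the interactions were added after the data were seen. Whether numbers pair libraries was checked by correlating deviations from group means. In brown fat all 3 same-numbered pairs of lunar and Earth libraries correlated at 0.118 to 0.217, above 0.1. The numbers were thus taken to pair them, though the labels do not say what the number marks. This pairing was inferred from the same data. The muscle share of brown fat fell in the order of replicates 1, 3 and 2 in both groups. It was 1.80%, 0.600% and 0.00442% in that order in lunar libraries and 3.23%, 1.37% and 0.00130% in Earth ones. Whether the correlations follow the muscle share or a true pairing was not tested. Libraries of unlike number reached 0.192 between lunar and Earth tendon and 0.262 between Earth tendon and Earth brown fat. No pair of libraries in a group was close to a duplicate: the mean squared difference of their counts was at least 24.2 times sampling noise.

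The tests were checked on simulated counts with 200 changed genes. At a 4-fold change 79 of 100 were recovered in the tendon (17170 genes), 98 in quadriceps (14529) and 82 in brown fat (14839), and at a 2-fold change 8, 85 and 15. Over 8 draws with a dispersion per gene, 8.68% of calls were false in the tendon, 5.90% in quadriceps and 6.38% in brown fat, above the nominal 5%; with a single dispersion trend the shares were 4.28%, 4.54% and 4.21%. For the interactions, 116 of 200 genes changed 4-fold in the tendon alone were recovered against quadriceps and 104 against brown fat (18829 genes), with 2 and 3 false calls.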

Results

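Gene expression was measured by RNA sequencing in 3 tissues of wild-type mice, the Achilles tendon, the quadriceps muscle and brown adipose tissue, under lunar or Earth gravity. Each of the 6 combinations of tissue and gravity held 3 libraries, 18 in all. Total estimated counts per library ran from 19662100 to 34373600. The labels do not say how lunar gravity was produced, how long it lasted, or whether replicates came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. Fold changes are given as log2 of lunar over Earth with the standard error of the fit. Levels of single genes are TMM-normalised CPM, counts scaled to library size, with the SD over 3 libraries. List levels, as mean log2 CPM, and muscle shares are scaled to the library total alone, without TMM factors. Adjusted p-values come from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment within each comparison.

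The first comparison asked which genes of the Achilles tendon differ between lunar and Earth gravity. The genes that passed as higher in the lunar libraries included some of skeletal muscle, of mitochondrial energy production and of glycogen use, and those that passed as lower included some of the collagen matrix and of tendon cells. Myh4, the myosin heavy chain of fast fibres, stood at 2274 ± 666 CPM under lunar gravity and 13.2 ± 17.0 CPM under Earth gravity (log2 fold change 7.43 ± 1.13, adjusted p = 0.0317). Npy, which encodes neuropeptide Y, fell by 4.63 on the log2 scale (SE 0.53, adjusted p = 0.0288), and Thbs1, which encodes a matricellular thrombospondin, fell from 319 ± 48.0 to 44.8 ± 16.4 CPM (adjusted p = 0.0288). Of 17692 genes tested, 239 were higher and 143 lower.

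Among the 79 nuclear-encoded members of the oxidative phosphorylation (OXPHOS) list, 6 rose, none fell and 73 did not pass; 34 rose when adjusted over the list alone. All 79 had a fold change above 0, with a mean of 1.31 (SD over members 0.53). Uqcrfs1, the iron-sulfur subunit of complex III, rose by 2.22 ± 0.42 (adjusted p = 0.0383), Atp5c1, a subunit of ATP synthase, by 2.15 ± 0.44 (adjusted p = 0.0446), and Ndufa9, a complex I subunit, by 1.90 ± 0.36 (adjusted p = 0.0381). As a list the group passed the camera test with a preset correlation (adjusted p = 7.51e-19) but not with an estimated one (adjusted p = 0.422 with an estimated correlation). In the TCA cycle list 3 of 23 members rose, among them Fh1 (1.70 ± 0.30) and Mdh2 (1.83 ± 0.37), and 19 rose adjusted over the list alone; in the fatty acid oxidation list 2 of 27 rose, Slc25a20 and Etfdh, and 16 adjusted over the list alone. For both lists the adjusted p was 0.393 with an estimated correlation. Ppargc1a, a coactivator of mitochondrial biogenesis, had a fold change of 3.64 ± 0.78 and did not pass (adjusted p = 0.0642).

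Transcripts of skeletal muscle moved with these groups. The muscle share of a library was taken as the median, over the contractile genes, of its CPM relative to the mean of the quadriceps libraries. It was 15.9%, 36.2% and 33.8% in the lunar tendon libraries and 0.150%, 0.0609% and 6.15% in the Earth ones. The quartiles over these genes were 8.96% to 39.5%, 18.4% to 75.5% and 15.8% to 50.5% in the lunar libraries. In the Earth ones they were 0.0224% to 0.219%, 0.00564% to 0.220% and 3.11% to 12.5%. The share is thus a rough measure. All 22 contractile genes had a fold change above 0 (mean 4.28, SD 0.76); 2 rose, Tpm2 and Myom1, and 6 adjusted over the list alone (adjusted p = 0.393 with an estimated correlation). The actin gene Acta1 stood at 7344 ± 4450 CPM in lunar and 265 ± 448 CPM in Earth libraries and did not pass (adjusted p = 0.299). Earth replicate 3 had the highest muscle share of its group and its highest mean OXPHOS level, 8.94 log2 CPM against 8.14 and 8.16. Its rank against the 8.84 of lunar replicate 1 is not settled. These levels are without TMM factors, which were 1.17 for Earth replicate 3 and 1.01 for lunar replicate 1. The quadriceps libraries stood lower on this list, at 7.90 to 8.47, than the lunar tendon libraries, at 8.84, 9.49 and 9.42, and the slow fibre genes stood at 5.46, 7.89 and 7.75 in lunar tendon against 5.03 to 5.69 in quadriceps. With the level of the contractile genes as a covariate, 1 gene was higher and 0 lower, and the mean fold change of the OXPHOS list was 0.25 (adjusted p = 0.569).

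**Figure D1:**
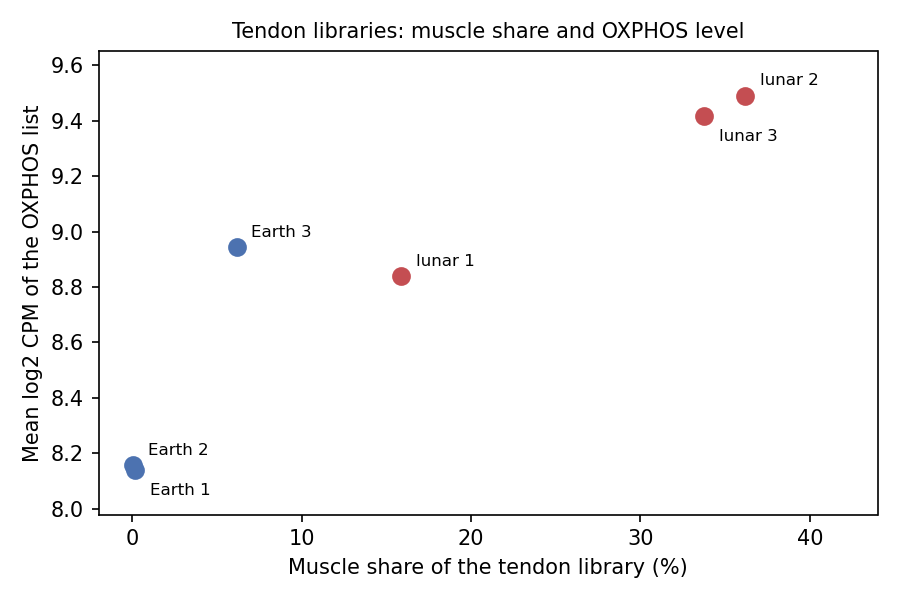
Mean log2 CPM of the 79 OXPHOS genes (vertical axis) against the muscle share in percent (horizontal axis) in the 6 tendon libraries, 1 point each, red for lunar and blue for Earth gravity. Earth replicates 1 and 2 sit below a share of 1% at 8.14 and 8.16. Lunar replicates 2 and 3 at shares of 36.2% and 33.8% sit at 9.49 and 9.42. Levels and shares are without TMM factors.

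In the glycogen metabolism list 7 of 13 members rose and 10 adjusted over the list alone, among them the phosphorylase kinase subunits Phkg1 (2.34 ± 0.35) and Phka1 (1.67 ± 0.30). In the heat shock list 5 of 19 rose, led by the small heat shock proteins Hspb7 (5.35 ± 0.74), Hspb6 (5.72 ± 0.97) and Cryab (4.74 ± 0.75), which are abundant in muscle. Other genes with large positive changes were Nos1, the neuronal nitric oxide synthase (5.60 ± 0.81), Cacng1, a calcium channel subunit of muscle (5.73 ± 0.94), and Fbp2, the muscle fructose bisphosphatase (5.78 ± 0.91). Of the 13 genes of myogenesis and denervation, Pax7 and Myog passed as higher and had no count in any Earth tendon library, so no fold is given, and Runx1 fell by 1.52 (SE 0.27). Both lists and the myogenesis list had an adjusted p of 0.393 with an estimated correlation. The muscle share stood as above beside all of these groups.

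Some matrix and tendon genes were lower. Of 31 fibrillar collagens and small proteoglycans 6 fell and 20 fell adjusted over the list alone, among them Col15a1 (fell by 1.74, SE 0.27), Fn1, which encodes fibronectin (fell by 1.76, SE 0.31), and Col12a1 (fell by 1.61, SE 0.31). Col1a1, the main collagen of tendon, stood at 372 ± 181 CPM against 1525 ± 198 CPM and did not pass (adjusted p = 0.0507), nor did Col3a1 (adjusted p = 0.0638). Of 23 collagen processing genes 5 fell and 9 adjusted over the list alone, among them Pcolce2, an enhancer of procollagen cleavage (fell by 1.99, SE 0.27), and the cross-linking enzyme Lox (fell by 1.75, SE 0.32). Of 23 tendon identity genes 6 fell and 14 adjusted over the list alone, among them Ccn2 (fell by 2.30, SE 0.39) and Cilp2 (fell by 2.72, SE 0.56). The tendon transcription factors Scx (1.54 ± 0.62, adjusted p = 0.219) and Mkx (-1.60 ± 0.45, adjusted p = 0.0965) and the marker Tnmd (-1.26 ± 0.38, adjusted p = 0.115) did not pass. Of 8 chondrocyte markers Comp and Col11a1 fell, 7 adjusted over the list alone. These 4 lists had an adjusted p of 0.393 with an estimated correlation. Markers of other cells went both ways, and no list of them passed with an estimated correlation. Above 0 were 7 of 8 mast cell markers (mean 1.00, SD over members 0.85), 11 of 12 Schwann cell and nerve markers (mean 0.57, SD 0.40) and 5 of 6 erythroid markers (mean 0.67, SD 1.25). Below 0 were 10 of 14 endothelial markers (mean -0.11, SD 0.27) and 6 of 10 fibroblast and adipocyte progenitor markers (mean -0.10, SD 0.42).

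The tendon counts rest on single libraries. Lunar replicate 2 stood apart, with a TMM factor of 0.624 against 0.940 to 1.27 in the other tendon libraries. Haemoglobin genes took 2.48% of its counts against 0.795% to 1.18% in the others. Without Earth replicate 1 or Earth replicate 2 the counts higher and lower were 0 and 0, and without lunar replicate 2 they were 1 and 1. There were 563 higher without lunar replicate 1, 91 lower without lunar replicate 3, and 517 higher without Earth replicate 3. Leaving out both lunar replicate 2 and Earth replicate 3, chosen after the data were seen, gave 347 higher and 53 lower.

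The second comparison asked the same of the quadriceps. Genes of protein quality control rose: all 31 proteasome genes tested were higher, and 15 of 19 heat shock genes, with 18 adjusted over the list alone. Psmd11, a regulatory subunit of the proteasome, rose by 1.13 ± 0.12 (adjusted p = 0.000134), and Psma7, a core subunit, went from 152 ± 10.9 to 308 ± 15.2 CPM. Hspa1b, an inducible HSP70 gene, rose by 3.88 ± 0.46 (adjusted p = 0.00568), its near-identical copy Hspa1a by 3.42 ± 0.45, so that reads may be split between them, and the co-chaperone Dnajb1 by 3.72 ± 0.53 (adjusted p = 0.0151). Csrp3, a Z-disc protein that responds to muscle load, rose from 339 ± 22.1 to 1696 ± 175 CPM (log2 fold change 2.33 ± 0.12, adjusted p = 5.68e-07). Of 14872 genes tested, 743 were higher and 458 lower.

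Of 24 immediate early genes 12 rose and 14 adjusted over the list alone, among them Myc (1.71 ± 0.20), Jun (1.29 ± 0.16) and Btg2 (1.19 ± 0.19); the stress factor Atf3 rose by 2.60 ± 0.32. In the unfolded protein response list 10 of 20 rose, among them the chaperone Hspa5 (1.01 ± 0.14) and Atf4 (0.61 ± 0.11), and 1 fell, Chac1 (fell by 2.65, SE 0.50). Among 21 load-responsive genes 6 rose, including Ankrd2 (1.64 ± 0.14), Xirp1 (2.11 ± 0.18) and Ccn1 (2.08 ± 0.22). Of 15 genes of myogenesis and denervation 5 rose, including Myog (1.57 ± 0.19) and Musk, the receptor kinase of the neuromuscular junction (1.24 ± 0.17). The clock genes Cry2, Per2 and Cry1 rose. The ubiquitin ligase Trim63 rose by 0.67 ± 0.18 (adjusted p = 0.0449) with overlapping groups, and Fbxo32 stood at 412 ± 80.4 and 413 ± 165 CPM.

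Some collagen, tendon and energy genes were lower in lunar quadriceps. Of 31 collagens and proteoglycans 10 fell and 17 adjusted over the list alone, among them Col1a2 (fell by 1.17, SE 0.15), Col1a1 (fell by 1.09, SE 0.16) and Col3a1 (fell by 0.98, SE 0.16). Beside them all 10 fibroblast and adipocyte progenitor markers had a fold change below 0 (mean -0.31, SD over members 0.20), none passing, as had 12 of 14 endothelial markers (mean -0.22, SD 0.26), 1 passing, with adjusted p = 0.672 and 0.474 with an estimated correlation. Of 23 tendon identity genes 7 fell, among them Comp, Chad and Kera, and 1 rose. In the OXPHOS list 9 of 79 fell and 13 adjusted over the list alone, with a mean fold change of -0.23; Sdhd, a subunit of complex II, fell by 0.63 (SE 0.09, adjusted p = 0.00154). In the TCA cycle list 4 of 23 fell. Amd1, which encodes an enzyme of polyamine synthesis, fell by 1.65 (SE 0.11, adjusted p = 3.76e-06). No list passed with an estimated correlation, where the proteasome came nearest (adjusted p = 0.0537 with an estimated correlation, heat shock 0.218, immediate early genes 0.254, OXPHOS 0.672). Without lunar replicate 2 the counts were 442 and 222, without Earth replicate 2 they were 376 and 183, and without Earth replicate 3 they were 451 and 219; with the spread estimated over all 18 libraries they were 32 and 8.

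**Figure D2:**
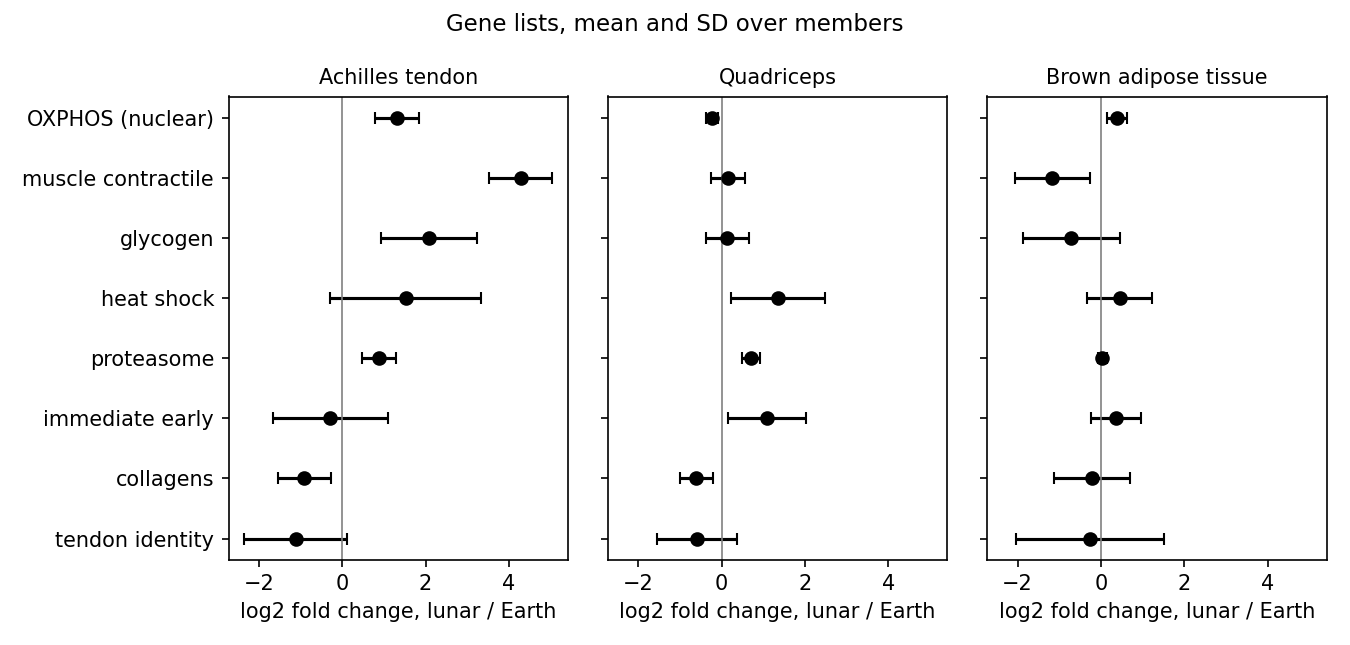
Mean log2 fold change of lunar over Earth (horizontal axis) for 8 gene lists (vertical axis) in the 3 tissues, with bars for the SD over list members, which is not an error over libraries. The OXPHOS list lies at 1.31 in the tendon, -0.23 in quadriceps and 0.39 in brown adipose tissue, and the contractile list at 4.28 in the tendon.

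The third comparison asked the same of brown adipose tissue, the heat-producing fat. No gene of 15538 passed the edgeR test in either direction, with a smallest adjusted p of 0.185; 1450 genes had an unadjusted p under 0.05, DESeq2 called 155 higher and 138 lower, and limma-voom 7 and 0. Same-numbered lunar and Earth libraries deviated together in this tissue, and with the replicate number as a block 38 genes were higher and 14 lower. The genes of smallest p, none of them passing, were Nnmt (137 ± 46.2 against 21.8 ± 5.02 CPM), Noct, Pck1, Arxes2 and Hp on the higher side and Olfr1396, mt-Rnr2, Odad4, Aspg and Cep170b on the lower side. Ucp1, the uncoupling protein of heat production, stood at 2251 ± 1029 and 911 ± 531 CPM (adjusted p = 0.469).

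Counts in mitochondrially encoded genes, ribosomal RNAs included, took 21.3%, 26.9% and 26.9% of the lunar and 38.0%, 38.6% and 37.9% of the Earth brown fat libraries. The ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 6.44%, 7.20% and 7.44% of the lunar and 13.8%, 13.1% and 11.1% of the Earth libraries. None of the 13 mitochondrially encoded genes listed passed over all genes, and 11 fell adjusted over the list alone. Among 27 fatty acid oxidation genes none passed over all genes and 10 rose adjusted over the list alone, with a mean of 0.71. Of 17 adipocyte genes 6, and of 19 thermogenesis genes 3, rose adjusted over the list alone, while 5 of 19 lipogenesis genes fell so. Markers of other cells went both ways, with none passing over all genes: 13 of 14 endothelial markers (mean -0.35, SD over members 0.23) and all 7 erythroid ones (mean -0.65, SD 0.26) had a fold change below 0, while 10 of 14 macrophage markers (mean 0.36, SD 0.80), 3 of 5 neutrophil markers (mean 1.08, SD 2.38) and 6 of 10 fibroblast and adipocyte progenitor markers (mean 0.29, SD 0.53) had one above 0. The mean of the OXPHOS list was 0.39, and 0.149 without Earth replicate 3, 0.245 without lunar replicate 1 and 0.743 without Earth replicate 1. Without TMM factors its level was higher in the lunar library of each numbered pair (9.07 against 8.47, 8.70 against 7.93 and 8.46 against 7.44 log2 CPM). The TMM factors, 1.16, 1.09 and 1.12 in lunar and 0.845, 0.889 and 0.932 in Earth libraries, narrow these gaps. With an estimated correlation no list passed (adjusted p = 0.655 with an estimated correlation for the fatty acid oxidation, mitochondrially encoded, adipocyte, thermogenesis, endothelial and erythroid lists, and 0.706 for lipogenesis). The preset correlation passed 27 lists in the tendon, 25 in quadriceps and 21 in brown fat, and the same test passed up to 31, 20 and 24 lists in other splits of the same 6 libraries, and up to 19 in those that part the numbered brown fat pairs.

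**Figure D3:**
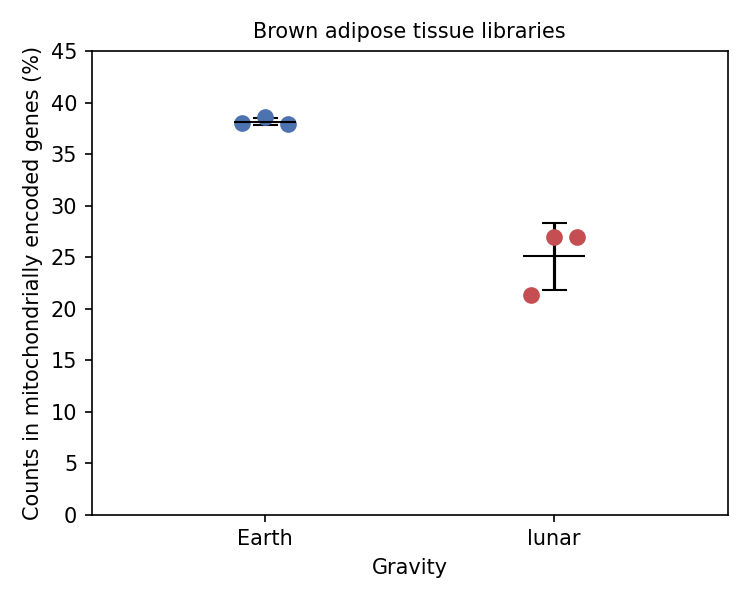
Percent of counts in mitochondrially encoded genes (vertical axis, from 0) in the 6 brown adipose tissue libraries by gravity (horizontal axis), 1 point per library, with the mean as a dash and the SD as a bar (n = 3 per group). The Earth libraries lie between 37.9% and 38.6%, above the lunar ones. The share includes the mitochondrial ribosomal RNAs.

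The last comparison tested whether the lunar effect differed between tissues, as an interaction over all 18 libraries. The effect of 353 genes differed between tendon and quadriceps, 289 of them with the greater value in the tendon. Ldhb, a subunit of lactate dehydrogenase, had a fold change of 2.97 in the tendon and -0.95 in quadriceps (difference 3.90 ± 0.57, adjusted p = 0.00503), and Dnajb1 had 0.04 and 3.72 (difference -3.69 ± 0.48, adjusted p = 0.00343). Between tendon and brown fat 411 genes differed, among them Thbs2 (-1.58 and 3.02), and between quadriceps and brown fat 10; with the replicate number of the brown fat libraries as a block these 2 counts were 627 and 89. The OXPHOS list differed by a mean of 1.53 between tendon and quadriceps (adjusted p = 0.248 with an estimated correlation). The muscle share of the tendon libraries, above, moved with these tendon differences. Any 1 of the 12 libraries left out moved the first count by over 1.5 times, from 82 without lunar quadriceps replicate 2 to 622 without lunar tendon replicate 1. The count for tendon and brown fat was 635, 138, 183, 173, 200 and 273 without lunar tendon replicates 1 and 2, Earth tendon replicates 1 and 2, and lunar brown fat replicates 2 and 3, each left out alone. The count for quadriceps and brown fat was 1 without lunar quadriceps replicate 2, Earth replicate 2 or Earth replicate 3, 3 without Earth quadriceps replicate 1, 6 without lunar quadriceps replicate 3, and 41, 38, 21 and 18 without lunar brown fat replicate 3 and Earth brown fat replicates 1, 2 and 3. Tendon and quadriceps shared 55 genes called higher, where independent lists would share 12.1 (Fisher's exact test, p = 7.97e-22). They shared 14 called lower, against 3.83 (Fisher's exact test, p = 2.89e-05). The test takes genes as independent and does not measure the spread between libraries. Among the 55 were muscle genes such as Cryab, Myog, Myom1 and Cacng1, and the muscle share of the lunar tendon libraries stood as above beside them. Among the 14 were Cilp, Cilp2 and Comp of the tendon identity list and Col1a2. The level of that list in quadriceps was 3.04, 3.14 and 3.69 log2 CPM in lunar and 3.94, 3.88 and 3.79 in Earth libraries. Whether the quadriceps samples differed in the tendon tissue they held was not tested.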

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

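The tests of muscle carry-over by the side of the tissue on which a gene is higher, of muscle like the quadriceps, of dilution and of whole-animal stress were chosen after the tables of genes had been seen, and the subtraction of muscle reads and the block within brown fat were added then too. The counts and genes of the next paragraph were picked out because the lunar effect differed between tissues by a test of the difference itself; the 3 patterns after it are results of gene lists within a tissue and were not.

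The lunar effect differed between tendon and quadriceps for 353 genes, between tendon and brown fat for 411 and between quadriceps and brown fat for 10. In 50 splits of the libraries within each tissue, the real one included, 2 gave as many genes for each pair, the real one among them, and the highest of the others were 535, 900 and 12. These splits take no account of the numbers taken to pair the brown fat libraries. With those numbers as a block, over 50 splits that part all 3 pairs, tendon and brown fat differed for 627 genes, 3 splits gave as many and the highest other was 1214; quadriceps and brown fat differed for 89, 1 split, the real one, gave as many and the highest other was 41. For tendon with quadriceps and for quadriceps with brown fat, each taken alone, under 5% of the splits thus gave as many genes. For tendon with brown fat this did not hold once the pairing is kept. The splits stand for no difference between gravity groups in either tissue. They argue against that for the first 2 pairs named, but cannot test whether an effect differs between tissues. The splits with the highest counts kept a real gravity split in at least 1 of the 2 tissues, as it was or turned round, and among those that kept it in neither the highest counts were 1, 4 and 4 without the block and, for the 2 pairs with brown fat, 9 and 7 with it. Greater in the tendon than in quadriceps were Ldhb (3.90), H1f2 (1.85), Tmem182 (2.98), Apoo (2.81) and Mtfp1 (3.58), and lower were Dnajb1 (-3.69), Thbs1 (-3.79), Arid5b (-2.19), Prg4 (-2.78) and Wwp2 (-2.19). Greater in the tendon than in brown fat were Prkag3 (10.02), Ttll7 (4.05), Fbp2 (6.48), Nol3 (2.60) and Gdpd1 (3.90), and lower were Thbs2 (-4.60), Pcolce2 (-4.08), Cdon (-3.69), Fbln7 (-4.13) and Pdgfrl (-5.16). Greater in quadriceps than in brown fat were Dnajb1 (2.92), Arid5b (2.21) and Mapre2 (1.66), and lower were Amd2 (-1.83), Amd1 (-1.91), Pdgfrl (-4.85), Thbs2 (-3.14) and Zc2hc1c (-5.98). Zc2hc1c did not pass the count filter in brown fat alone, and Prkag3 and Pdgfrl had few or no counts in 1 brown fat group, so the sizes of these 3 differences are uncertain. Amd1 and Amd2 are close copies, between which reads may be split.

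The first pattern weighed is the higher level of energy and muscle genes in lunar tendon. A difference in depth is argued against, since the totals of the groups overlap (the smallest total of one group is at most 0.912 times the largest of the other). Skeletal muscle carried over into the sample is consistent with the tables: the contractile list had a mean fold change of 4.28 where the OXPHOS list had 1.31, though few members of either passed, and 92.5% of the 239 genes called higher stood higher in quadriceps than in Earth tendon, against 36.3% of all genes tested and 2.10% of the genes called lower. The Earth tendon level enters both the calls and that comparison, which pushes the 92.5% up and the 2.10% down whatever the cause. With the contractile level as a covariate the OXPHOS mean was 0.25. That level separates the groups (8.11 to 9.34 log2 CPM in lunar and 1.79 to 6.66 in Earth libraries), so the covariate removes gravity along with muscle. With muscle reads subtracted the OXPHOS list had a mean of 0.0513 (SD over members 4.64) and a median of 1.58, and the preset test still passed it as higher (adjusted p = 5.65e-06), but the subtraction took 749 of 17506 expressed genes to 0 in every lunar tendon library, so it removes too much and decides nothing. Levels were also set against muscle with the expression of the quadriceps. In lunar tendon 60 of the 79 OXPHOS genes stood higher than in both Earth tendon and quadriceps. A mixture of the 2 reaches a list mean of at most 8.76 at any 1 share. Each lunar library lay above that bound, by 0.489 on average, though the 95% interval over the 3 libraries held 0 (-0.397 to 1.38). Earth replicate 3, at 8.94, lay above it too. The lunar mean lay 0.0308 below a looser bound that takes the larger of both for each gene. Other energy and muscle lists stayed below that mixture bound, as muscle like the quadriceps requires: the TCA cycle by 2.53 (95% interval of the excess -2.79 to -2.28, 0 of 23 genes above both tissues), glycogen metabolism by 3.41 (-3.68 to -3.14, 0 of 13), fatty acid oxidation by 1.30 (-1.61 to -0.994, 5 of 27) and the contractile genes by 1.74 (-3.32 to -0.166, 4 of 22); their bound is reached at a share of 100%, so it is a wide one. The slow fibre genes lay above their bound by 1.62 (-1.76 to 4.99, 9 of 14) and above the looser one by 1.19. The complex IV part of the OXPHOS list did so by 0.724 (-0.729 to 2.18, 12 of 14) and by 0.665. Earth replicate 3 stood above these mixture bounds too, at 5.57 against 5.35 for slow fibre genes and 10.3 against 9.65 for complex IV. The OXPHOS levels thus cannot decide whether muscle like the quadriceps is the whole cause of that list. The 4 lists below their bound cannot decide it either, since that bound is quadriceps alone. A mixture at the lunar muscle shares, 15.9% to 36.2%, stays below it in any case. In lunar replicates 2 and 3 the slow fibre genes stood at 7.89 and 7.75, above every quadriceps library (5.03 to 5.69). Their excess over the mixture bound was 2.48 and 2.32 there, against 0.0523 in lunar replicate 1. For lunar replicates 2 and 3 this argues against muscle like the quadriceps as the only source of slow fibre transcripts. Muscle of another kind, such as one richer in slow fibres, was not analysed here. An effect of gravity on energy genes of the tendon itself stays open, since gravity and muscle share cannot be separated in 3 libraries per group.

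The second pattern is the lower level of collagen and tendon genes in lunar tendon. Dilution by muscle RNA may lower them. With muscle reads subtracted the fibrillar collagen list still had a mean of -0.73, against -0.92 before, and still passed the preset test. That outcome had been written down as counting against dilution, though after the tables of genes had been seen. The subtraction removes too much, as above, and is set aside. Muscle RNA only adds to what dilution leaves, so under dilution alone no list falls further than genes near absent from quadriceps (415 genes, median -0.11). The median of the fibrillar collagens lay below that by 0.80 (difference -0.80, SE over members 0.11), of collagen processing by 0.56 (-0.56, SE 0.14), of tendon identity by 1.14 (-1.14, SE 0.26) and of chondrocyte markers by 2.49 (-2.49, SE 0.29). In all 4 lists this difference was lower in every lunar library than in every Earth one, for the chondrocyte markers -0.353 at most against 0.648 at least. The members near absent from quadriceps, 1, 1, 5 and 4 genes, had medians of -1.92, -2.19, -2.66 and -2.65. Taken over genes, these values lie lower than dilution by muscle like the quadriceps leaves. Over the 3 libraries per group, though, the Welch 95% intervals of the differences held 0, at -1.50 to 0.0162, -1.26 to 0.172, -2.36 to 0.101 and -4.65 to 0.0777; with levels not centred by gene the first 3 again held 0 and the chondrocyte interval, -3.19 to -0.468, did not. The comparison also takes the muscle to be like the quadriceps. The OXPHOS levels above could not decide that, and the slow fibre levels of lunar replicates 2 and 3 argue against it. The falls themselves, against 0, had adjusted p-values of 0.0696 to 0.0783 with fry. The rule set for this test asked for centred intervals below 0, so dilution as the whole cause of the 4 lists is not decided. The muscle profile is not known either. An effect of gravity on these lists stays open beside dilution, and a difference in the mix of cells was not tested.

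The third pattern is the rise of immediate early genes in lunar quadriceps, where heat shock genes rose too. A stress response of the whole animal at collection could raise the immediate early genes in every tissue. Their mean was -0.28 in the tendon (SE over members 0.28) and 0.35 in brown fat (SE 0.13), so the tendon value lies within its spread and the explanation stays open. The heat shock list had means of 1.52 in the tendon (SD over members 1.82), beside the muscle transcripts there, and 0.45 in brown fat (SD 0.79), while its member Dnajb1 had 0.04 in the tendon, 0.78 in brown fat and 3.72 in quadriceps, and differed between tendon and quadriceps (adjusted p = 0.00343), so these values go both ways. An effect of gravity on the muscle is also open and was not tested apart from it.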

How the results depend on the processing

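With 3 libraries per group and 10 splits of each tissue, no share of splits can fall under 0.05. In the tendon the real split alone called genes (1 of 10 splits; 382 genes against a highest other of 0), and in quadriceps too (1 of 10; 1201 against 0), while in brown fat all 10 splits called 0. For lists past the preset test 5 of 10 splits passed as many in the tendon (27, highest other 31), 1 of 10 in quadriceps (25, highest other 20) and 4 of 10 in brown fat (21, highest other 24). The OXPHOS mean lay as far from 0 in 1 of 10 tendon splits (1.31, highest other 1.25), 2 of 10 in quadriceps (highest other 0.313) and 4 of 10 in brown fat (highest other 0.715). The 10 brown fat splits take no account of its numbered pairs; of the 4 that part all 3 pairs, too few for a share under 0.05, the real one passed 21 lists against 7, 7 and 19 and had an OXPHOS mean of 0.39 against 0.036, 0.0715 and -0.275. For the shared calls of tendon and quadriceps, 69 in the real pair of splits, 1 of 100 drawn pairs, the real one, shared as many and the highest other was 0; since no other split of either tissue called a gene, no other pair could share one, and this count says nothing about chance.

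DESeq2 called 1214 higher and 576 lower in the tendon, 712 lower in quadriceps and 155 and 138 in brown fat, with 876, 1103 and 301 genes differing between tendon and quadriceps, tendon and brown fat, and quadriceps and brown fat, and 274, 43 and 33 shared calls for those pairs. Without a low-count filter the tendon had 596 and 291, quadriceps 815 lower, brown fat 27 and 4, and the last interaction 74. The stricter filter gave 239 lower in the tendon and 1 higher in brown fat. Limma-voom gave 662 and 292 in the tendon, 7 higher in brown fat, and 1505, 232 and 41 interactions. A single fit of all 18 libraries gave 1104 and 327 in the tendon, 32 and 8 in quadriceps, and 65 and 31 in brown fat, the spread then being shared by the tissues. The contractile covariate left 1 and 0 genes and 13 lists in the tendon, with an OXPHOS mean of 0.25. Subtracting muscle reads, chosen after the data were seen, gave 4 and 239 with an OXPHOS mean of 0.0513. Leaving out lunar replicate 2 with Earth replicate 3, also chosen then, gave 347 higher and 53 lower. With an estimated correlation 0 lists passed in each tissue and the OXPHOS means of 1.31, -0.23 and 0.39 did not pass; with fry 0, 10 and 0 lists passed and the same means did not. Apart from the settings named, the cause was not tested.

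With each library left out in turn, the tendon gave 0 to 563 higher and 0 to 161 lower, and quadriceps 376 to 602 and 183 to 347. Brown fat gave 0 to 2 higher, with an OXPHOS mean of 0.149 to 0.743, and the 3 interactions gave 82 to 622, 138 to 635 and 1 to 41. Fewer libraries weaken each test, which does not account for the counts that rose. Ranges that crossed 0 were, in the tendon, Mt2 -0.59 to 0.33, Mt1 -0.29 to 0.51 and Cdkn1a -0.66 to 0.0543; in quadriceps, Arntl -0.21 to 0.0422, Scx -0.37 to 0.18, Fbxo32 -0.26 to 0.34, Dbp -0.44 to 0.22, Acta1 -0.12 to 0.0348, Per1 -0.0208 to 0.58 and Mkx -0.76 to 0.0767; and in brown fat, Myh7 -1.77 to 2.10, Col1a1 -0.24 to 0.25 and Acta1 -2.88 to 3.5e-05. None of these passed in the main test.

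With the replicate block, brown fat had 38 higher and 14 lower; of the 4 splits that part all 3 of its numbered pairs, the other 3 gave 0. A block within brown fat alone, chosen after the data were seen, gave 627 genes for tendon with brown fat and 89 for quadriceps with brown fat. The block gave 205, 170 and 1 genes for the interactions, with number and gravity taken as an animal, where same-numbered libraries of different tissues did not deviate together (r from -0.184 to 0.210). In quadriceps (r -0.0595 to 0.000109) and the tendon (r -0.134 to 0.174) the numbers were not taken to pair the libraries. The block moved neither count of calls there by over 1.5 times.

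Other values that turned sign were these. Tendon Mt1 was -0.0305 with limma-voom, -0.14 with the replicate block and -0.19 without both lunar replicate 2 and Earth replicate 3. With the covariate, tendon Trim63 was -0.00544, Myh7 -3.83, Dbp -0.82, Cdkn1a 1.18 and Mt2 0.24, and brown fat Myh4 0.26 and Ckm 0.82. With muscle reads subtracted, tendon Hspb8 was -2.12, Slc25a20 -1.27, Gyg -2.80, Uqcrfs1 -0.0424, Mdh2 -0.15, Idh3b -1.24, Acadvl -12.36, Cdkn1a 0.21 and Mt2 0.47. Quadriceps Fbxo32, at 0, was 0.00245 with DESeq2 and with RLE scaling, 0.000192 without mitochondrial and haemoglobin genes, 0.00739 with all libraries and 0.0675 with the block; with limma-voom quadriceps Ucp1 was 0.79 and Scx 0.00612, and brown fat Myh4 1.10 and Ckm 1.43. Brown fat Col1a1 was 0.0214 without a filter and 0.0304 with the block.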

Other observations

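The brown fat libraries held skeletal muscle transcripts at low shares, 1.80%, 0.00442% and 0.600% under lunar and 3.23%, 0.00130% and 1.37% under Earth gravity. The mean fold change of the contractile list there was -1.17, while that of the OXPHOS list was 0.39 (0.149 to 0.743 with 1 library left out). Muscle carried over could not raise the OXPHOS list of brown fat in that direction.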
